A study of Mus musculus with 127 samples.

How the data were processed

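The deposited files used here are index-sort exports of a cell sorter, with a row per well of a capture plate. Per the file headers, each value is the area reading of a detector for the cell sorted into that well. The deposited values are fluorescence and scatter intensity on a linear scale in arbitrary units, some of them below 0. Detector voltage, compensation, gating and antibodies are not given in the sources used here. The 64 exports without scatter also give the number of events recorded per well, a count that is 1 in nearly all wells. The submitters' processing notes name bcl2fastq, STAR 2.7.1a, featureCounts 2.0.0, SAMtools 1.10, UMI-tools 1.1.2, Scanpy 1.9.8 and the GRCm39 build for the sequencing data. Those data were not analysed here. Per the labels' protocols, bone marrow-derived macrophages were cultured in 10 ng/ml M-CSF, pHrodo-labelled apoptotic thymocytes were added for 3 or 24 h, and lungs and B16 tumours were dissociated before sorting.

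Gene-level tests had been planned in case the files held counts of genes. They did not, so no gene test was run, and no detector name identifies an antigen, so no cell type markers were scored. Groups and replicate numbers were taken from sample titles. Of 127 samples, 73 had a file here, in 12 of 15 groups. Lungs given PBS and the rodo- gates of the E. Coli and Zymo groups were not analysed here. In 28 of 28 libraries whose header names a gate, time or tube, the header matched the label. Of 12 E. Coli and Zymo libraries whose header holds a replicate number, 8 carried another number than the title, so these numbers were not taken to pair samples. Per the file headers, the gates of an in vitro number and time share a day and tube, as do those of a B16 number except viable only, which came from another tube. Labels do not say which experiments used separate mice or cultures, so p-values measure the spread between experiments, which may in part be technical.

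The exports were of 2 kinds, 64 files with fluorescence alone and 9 files (lung thymocyte replicate 2 and E. Coli replicate 2) that also held forward and side scatter. Filters differ between these kinds. Detectors were matched between them by laser and nearest filter only for summaries by library and for correlations, and no difference was taken across the kinds. Scatter readings of E. Coli replicate 2 reach the top of the scale in 7.65% to 18.4% of the wells of a library. No pair of YG and R670 readings recurred between files, so no file was a copy of another.

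Wells with more than 1 recorded event were left out (28 wells in 10 libraries), a choice made after the files had been seen. Each library has 356 to 380 wells, which makes the library median precise, and the limit on precision is the number of experiments. Readings were transformed as asinh(value/150), the median was taken over wells, library medians were averaged per experiment, and group means over experiments were compared by a two-sided exact permutation test. This test does not pair the gates of an experiment, so levels that differ between experiments can raise its p. The sign-flip test of the replicate block pairs them. Percent differences are of mean library medians and take the detector's zero as given. Benjamini-Hochberg adjustment was made over the detectors of a comparison, for p-values over libraries permuted within experiments. Between gates YG was left out of it after the values had been seen, because the sort sets that difference, but not for rodo- against viable only, where no gate puts rodo- above viable only. These p-values treat plates as replicates and are too small as evidence about experiments. The separation of gates was given as the percent of pairs of cells, 1 from each gate, in which the cell of the first gate was brighter. Change of a gate difference with time was tested with 100000 permutations of times within gates and experiments, whose null is no change with time in either gate. The rule on naming, set with the tests and most alternatives before the data were examined, was that every detector with the same header name in both groups is named, the dye detector first, then scatter, then the rest.

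The test over libraries was tested on simulated data modelled on the in vitro gates, as 2 experiments of 4 and 3 libraries, with 200 simulations each. With no shift 6.5% were called, with an asinh shift of 0.1 it was 67.5% and with 0.3 it was 100%. Simulated plates were independent, so these rates do not cover a drift between plates that goes with the gate. The alternatives were cofactors of 5 and 1000, log10 with values under 1 set to 1, the mean over wells, leaving out extreme wells, equal weight for libraries in the share of pairs, libraries as replicates, the replicate block, and leaving out each experiment or library. For correlations they were Pearson's r and taking out forward scatter. Keeping wells with more than 1 event, using only the plates next to the change of gate, leaving out E. Coli and Zymo experiments singly, permuting lung libraries within recording sessions, and the ratio of the 95th percentile to the median were added after the data had been seen. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.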

Results

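The series concerns mouse macrophages that had or had not taken up apoptotic cells, a process called efferocytosis. Bone marrow-derived macrophages were kept for 3 h or 24 h with apoptotic thymocytes carrying pHrodo, a dye that brightens in acid compartments such as the phagosome. Cells were also sorted from mouse lungs and from B16 tumours, which grow from a melanoma line. The labels name the sort gates phago, non-phago, rodo+, rodo-, rodo high and viable only, the last for cells from tumours that received no added apoptotic cells. The data held here were the cytometer's readings of the single cells sorted into plates, not the RNA of those cells. In vitro they covered 7 phago and 6 non-phago libraries at 3 h, and 6 phago and 7 non-phago libraries at 24 h. From B16 tumours there were 6 rodo high, 8 rodo+, 4 rodo- and 4 viable only libraries. From lungs there were 8 phago and 2 non-phago libraries of mice given thymocytes, 9 rodo+ libraries with E. Coli and 6 with Zymo. These are 73 of 127 libraries, each library being a plate with 356 to 380 wells used, each with the readings of a sorted cell, and 27651 wells in all. Experiments (the replicate numbers of the titles) were taken as replicates. With 2 or 3 experiments per group no comparison could reach p = 0.05, since the smallest exact p was 0.333 for 2 against 2 and 0.1 for 3 against 3. Values are means ± SD over the libraries of an experiment of the library median, in arbitrary units, and p-values over libraries measure only the spread between plates of an experiment.

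No header names a dye, so the detector that followed the gate was found from the readings, after they had been seen. On the detector excited by the yellow-green laser (YG), the lowest cell of the positive gate lay above the highest cell of the negative gate in 6 of 6 comparisons within an experiment. On R670 and V431 the gates overlapped in all 6, and on B530 in 4 of 4. The YG difference between gates is therefore set by the sort and gives the YG brightness that each gate held. It does not measure the amount of dye, since pHrodo brightens in acid. The other detectors are named by laser letter and filter centre, and no header says what they stained. R670 had a floor in vitro, where the lowest reading of a gate lay between 6474 and 8411 in all 8 sets of libraries, so that cells dim on R670 were absent.

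**Figure D1:**
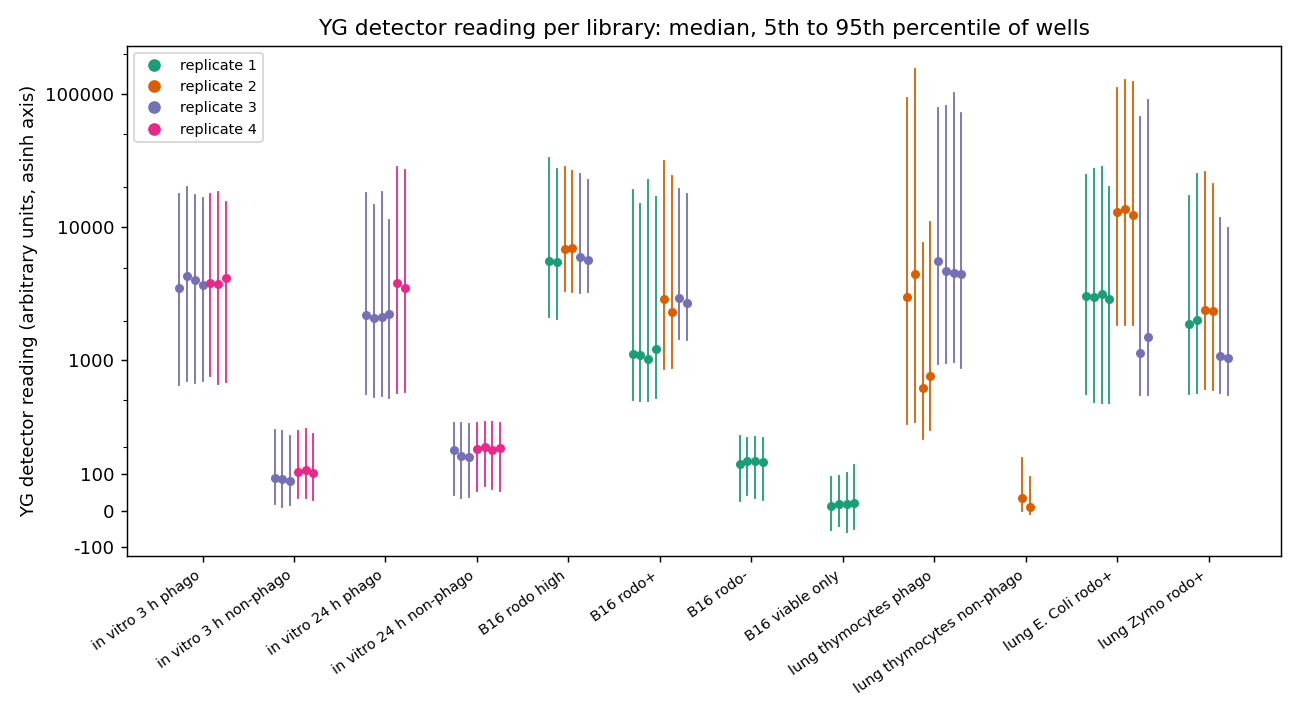
Reading of the YG detector (vertical asinh axis, arbitrary units) for each library of the 12 groups with files; points are medians over wells, lines run from the 5th to the 95th percentile of wells, and colours mark the experiment. The in vitro phago libraries lie far above the non-phago ones at both times, and the B16 rodo- libraries lie above the viable only libraries but under rodo+.

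After 3 h with apoptotic thymocytes, macrophages of the phago gate were far brighter on YG, as the sort set, and also brighter on every other detector measured. The YG median was 3882 ± 357 (SD, n = 4 libraries) in phago cells of replicate 3 against 85.2 ± 4.75 (SD, n = 3) in non-phago cells, and 3922 ± 204 (SD, n = 3) against 108 ± 4.26 (SD, n = 3) in replicate 4. R670 was 13.3% higher in phago cells of replicate 3 and 11.7% higher in replicate 4. V431 was 12.0% and 10.5% higher. B530, recorded in replicate 4 alone, was 65.7% higher, at 1398 ± 137 (SD, n = 3) against 843 ± 41.8 (SD, n = 3). These shifts were small against the spread between cells, because a random phago cell was brighter than a random non-phago cell on R670 in 57.8% of pairs in replicate 3 and 56.4% in replicate 4. For V431 the share was 58.6% and 57.2%, and for B530 it was 67.3%. The mean difference of asinh medians over experiments was 3.34 ± 0.0831 (SD, n = 2) for YG, 0.117 ± 0.00998 for R670 and 0.0964 ± 0.00472 for V431. The two-sided exact permutation p over experiments was 0.333 for R670 and 0.667 for V431, and none is given for YG between gates, which the sort sets. This test leaves the gates of an experiment unpaired, so the differing V431 levels of the experiments enter its p. Paired by experiment, the exact sign-flip p was 0.5 for R670 and V431, the smallest possible. With libraries permuted within experiments, the exact p was 0.00143 for R670 and V431 (adjusted p = 0.00214 over the 3 detectors other than YG) and 0.1 for B530. Non-phago plates were always recorded after phago plates, so a drift between plates and the gate both enter the plate means. The step between the 2 plates next to the change of gate was larger than the largest step within a gate in 5 of 5 detector and experiment pairs other than YG. In replicate 3 the margin was small, at asinh steps of 0.104 against 0.101 within a gate for R670 and 0.0833 against 0.0703 for V431, so drift is not excluded there.

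After 24 h the same detectors were brighter in the phago gate, and the gap on R670 and V431 was wider than at 3 h in both experiments. YG was 2172 ± 70.4 (SD, n = 4) in phago cells of replicate 3 against 170 ± 13.1 (SD, n = 3) in non-phago cells, and 3662 ± 190.0 (SD, n = 2) against 193 ± 4.93 (SD, n = 4) in replicate 4. R670 was 30.1% and 24.0% higher in phago cells of replicates 3 and 4. V431 was 25.4% and 35.9% higher, and B530 was 37.2% higher in replicate 4. Phago cells were the brighter of the pair on V431 in 67.1% of pairs in replicate 3 and 72.1% in replicate 4. The differences of asinh medians were 2.61 ± 0.30 (SD, n = 2) for YG, 0.239 ± 0.0330 for R670 and 0.246 ± 0.0672 for V431, with a two-sided exact permutation p over experiments of 0.667 for R670 and V431. Paired by experiment, the exact sign-flip p was 0.5 for R670 and V431, the smallest possible. The exact p over libraries was 0.0019 for R670 and V431 (adjusted p = 0.00286) and 0.0667 for B530. Whether the gap on R670 and V431 differed between the times was tested by permuting times within gates and experiments, and did not pass (permutation p = 0.205 and 0.124, adjusted p = 0.239 and 0.174 over 7 tests). In replicate 4 both detectors were higher at 24 h in both gates, and such a shared shift widens the spread of these permutations. Not passing therefore does not show an unchanged gap.

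**Figure D2:**
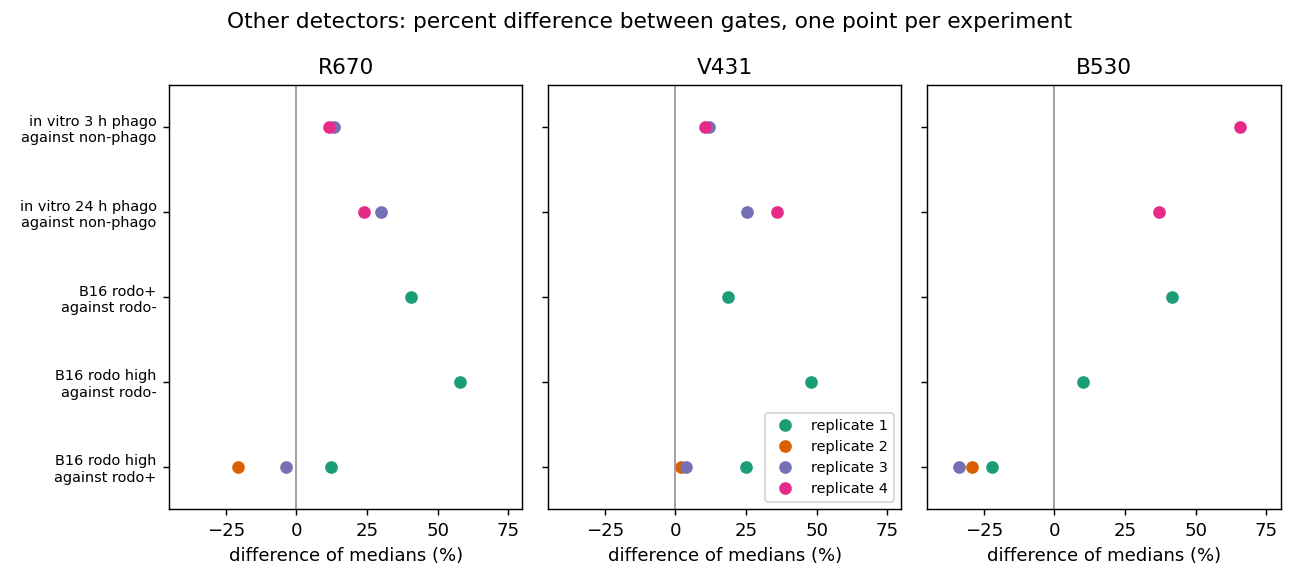
Difference of the mean library medians between gates in percent of the gate named after the word against (horizontal axis, %) for the detectors R670, V431 and B530; each point is 1 experiment, coloured by replicate number. In vitro points lie above 0 on all 3 detectors, while rodo high against rodo+ in B16 tumours lies on both sides of 0 for R670 and below 0 for B530 in 3 of 3 experiments.

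Between 3 h and 24 h the YG reading of phago macrophages was lower in both experiments and that of non-phago macrophages was higher in both. In phago cells the YG median was 3882 at 3 h and 2172 at 24 h in replicate 3, and 3922 and 3662 in replicate 4, where the asinh difference was -0.0682 and the SD over libraries 0.0512 at 3 h and 0.0518 at 24 h. In these cells the ratio of the 95th percentile to the median was 4.66 ± 0.338 (SD, n = 4) at 3 h and 7.22 ± 1.62 (SD, n = 4) at 24 h in replicate 3, and 4.42 ± 0.579 (SD, n = 3) and 7.61 ± 0.104 (SD, n = 2) in replicate 4 (exact permutation p over libraries = 0.00286, a measure chosen after the values were seen). The 95th percentile itself was 18039 at 3 h and 15635 at 24 h in replicate 3, and 17265 and 27859 in replicate 4, so in replicate 3 the higher ratio came with a lower median and not with brighter cells at the top. In non-phago cells the YG median was 85.2 at 3 h and 170 at 24 h in replicate 3, and 108 and 193 in replicate 4. Their ratio of the 95th percentile to the median was lower at 24 h, at 3.18 and 1.90 in replicate 3 and 2.55 and 1.70 in replicate 4 (exact permutation p over libraries = 0.00143), where the gate bounds the readings from above. The differences of asinh medians, 24 h minus 3 h, were -0.323 ± 0.360 (SD, n = 2) for phago and 0.416 ± 0.0237 (SD, n = 2) for non-phago cells, each with a two-sided exact permutation p of 0.333 over experiments. Over libraries the exact p was 0.00571 for phago (adjusted p = 0.0114) and 0.00143 for non-phago cells (adjusted p = 0.00571). R670 went apart between experiments: in phago cells it was 33.8% higher at 24 h in replicate 4 and lower in replicate 3 (percent difference -3.53). In non-phago cells it was 20.5% higher in replicate 4 and lower in replicate 3 (percent difference -16.0). V431 of phago cells was 3.95% and 43.4% higher at 24 h, V431 of non-phago cells was 16.6% higher in replicate 4 and lower in replicate 3 (percent difference -7.11), and B530 of replicate 4 was lower in both gates (percent differences -54.8 in phago and -45.4 in non-phago cells). The 2 times of an experiment were recorded on different days, so time and day cannot be told apart in these differences.

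In B16 tumours of replicate 1, the experiment with readings of all 4 gates used here, R670, V431 and V710 stood higher with each step of YG from rodo- to rodo high. YG was 16.7 ± 2.71 in viable only (SD, n = 4), 141 ± 4.74 in rodo- (SD, n = 4), 1114 ± 84.7 in rodo+ (SD, n = 4) and 5537 ± 60.7 in rodo high (SD, n = 2). In the same order R670 was 7685 ± 794, 10300 ± 261, 14473 ± 208 and 16268 ± 1004. V431 was 446 ± 114, 566 ± 19.6, 671 ± 7.72 and 838 ± 76.7. V710 did not follow the first step, at 12864 ± 1733 in viable only and 12264 ± 263 in rodo-, and was 15160 ± 159 in rodo+ and 18050 ± 1532 in rodo high. B530 was highest in rodo+, at 2878 ± 107, against 2035 ± 16.1 in rodo- and 2242 ± 166 in rodo high. All 5 detectors other than YG were higher in rodo+ than in rodo-, by 40.5% for R670, 18.6% for V431, 41.5% for B530, 26.7% for R780 and 23.6% for V710, each with an exact permutation p of 0.0286 over 4 against 4 libraries, the smallest these allow. This is 1 experiment, so these p-values compare plates and not tumours. At the change of gate the step between neighbouring plates exceeded the largest step within a gate on 4 of these 5 detectors. The exception was R780, where the step was 0.0604 against 0.0649 within a gate, and 0.139 over all plates. Plates were recorded in the order rodo+, rodo-, rodo high and viable only, and the rodo- plates lay under both their neighbours on R670, V431, V710 and B530.

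The rodo- cells, though below the gate, were brighter on YG than cells from tumours without added apoptotic cells. A reading over 104 units, which 5% of all viable only wells exceeded, was seen in 68.9% ± 2.16 (SD, n = 4) of rodo- wells and 5.04% ± 2.36 (SD, n = 4) of viable only wells. A rodo- cell was brighter on YG in 92.6% of pairs, and the asinh difference was 0.728 (exact permutation p over 4 against 4 libraries = 0.0286, adjusted p = 0.0571 over 6 detectors). R670 was 34.0% higher in rodo- and R780 was 96.3 ± 7.57 against 12.0 ± 30.04 (both with adjusted p = 0.0571, exact test). For V431 (adjusted p = 0.129), B530 and V710 (both adjusted p = 0.6, exact test) the asinh differences were below the SD between viable only plates. After adjustment no detector of this comparison passed 0.05, YG included. YG, R670 and R780 each reached an exact p of 0.0286, the smallest that 4 against 4 libraries allow. Their adjusted p is therefore set by the design and by the other detectors adjusted with them. Viable only also held dimmer cells, as its lowest reading was 2016 against 3791 in rodo- for R670. For V710 these were 3029 against 5176, and for B530 691 against 948, so cut-offs of the sort may enter these differences. Within viable only, V431 medians were 301, 419, 496 and 569 in recording order. R670 medians rose as well, from 7013 to 8822, and R780 medians fell from 52.2 to -19.2, so the R780 mean of 12.0 spans a trend between plates.

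Across 3 B16 experiments, rodo high cells differed from rodo+ cells on YG and on B530 in the same direction each time. YG was 5537 ± 60.7, 6915 ± 72.7 and 5873 ± 234 in rodo high of replicates 1 to 3 (SD, n = 2 each) against 1114 ± 84.7 (n = 4), 2615 ± 426 and 2828 ± 198 (n = 2 each) in rodo+, and the gates overlapped, with rodo high the brighter in 81.1%, 75.5% and 77.4% of pairs. B530 was lower in rodo high in 3 of 3 experiments (percent differences -22.1, -29.4 and -33.8), and the V431 median was higher in 3 of 3 (24.9%, 2.11% and 3.80%), although a rodo high cell was the brighter on V431 in only 50.6% and 49.7% of pairs in replicates 2 and 3. R670 was higher in replicate 1 (12.4%) and lower in replicates 2 and 3 (percent differences -20.8 and -3.74). V710 was 19.1% and 7.09% higher in replicates 1 and 3 and lower in replicate 2 (percent difference -10.1). The 2 experiments that recorded B710 had it 6.69% and 5.02% higher in rodo high. Over experiments the asinh difference was 1.104 ± 0.449 (SD, n = 3) for YG and -0.253 ± 0.0234 for B530, the latter with a two-sided exact permutation p of 0.5. This unpaired p takes in the differing B530 levels of the experiments. Paired by experiment, the exact sign-flip p for B530 was 0.25, the smallest possible. With libraries permuted within experiments the exact p was 0.00185 for B530 (adjusted p = 0.0111 over the 6 detectors other than YG) and 0.00741 for V431 (adjusted p = 0.0222). B530 readings lay below 0 in 28.5% and 27.8% of rodo high wells of replicates 2 and 3 and in 14.6% and 16.2% of rodo+ wells, but in no well of replicate 1. B530 also had bounds. In replicate 1 the lowest readings were 993 in rodo high and 974 in rodo+. The highest readings of replicate 2 were 511 in rodo high and 751 in rodo+, so the sort may in part set the B530 difference there. In replicate 3 the highest reading was 754 in each gate.

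In the lung, phago cells had higher mean medians than non-phago cells on all 6 detectors other than YG, forward and side scatter included, in the 1 experiment with readings of both gates used here (replicate 2). The size of the scatter difference was not the same in its 2 recording sessions. Both sessions had phago cells above non-phago cells on R670 (71.3% and 80.9% higher), V431 (143% and 704%), B530 (141% and 1586%) and R780 (101% and 163%). Forward scatter, which follows cell size, was 7.85% higher in phago cells of the first session and 103% higher in the second. Side scatter, which follows granularity, was lower by 0.405% in the first (percent difference -0.405) and 223% higher in the second. The gates held different shares of cells bright on B530. Divided at 454 units of B530, a division chosen after the values had been seen, 22.2% of phago and 1.84% of non-phago wells were bright in the first session, and 94.1% and 24.8% in the second. Among bright wells of the second session the gates lay close on V431 (675 in phago and 633 in non-phago) and on forward scatter (126721 and 121216), and among its dim wells V431 was 80 and 69. R670 was higher in phago cells in both of these classes (26289 against 20387 in bright and 27410 against 12809 in dim wells). Side scatter was higher in both too (82794 against 72765.5 in bright and 32549 against 18352 in dim wells), but lower in dim phago wells of the first session (29915 against 33841). In dim wells of the first session V431 was 175 in phago and 91 in non-phago cells, and forward scatter was 64485 and 62691. Among bright wells of that session, only 7 of them non-phago, V431 was 1030 in phago and 672 in non-phago cells, forward scatter 141750 and 117737, and R670 38945 and 28049. YG was 689.5 and 3729 in phago cells of the first and second session (means of 2 libraries each) against 34.0 and 9 in the single non-phago library of each. Over 4 phago and 2 non-phago libraries the exact permutation p was 0.0667 for R780, 0.133 for forward scatter, V431 and B530, and 0.2 for side scatter and R670 (adjusted p = 0.2 for each), where 0.0667 was the smallest possible. With libraries permuted within recording sessions, an alternative added after these values had been seen, the exact p was 0.111, the smallest possible, for each of these detectors but side scatter (0.222). Phago libraries of replicate 3, with no non-phago file used here, had a YG median of 4818 ± 553 (SD, n = 4).

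Lungs given E. Coli or Zymo particles were compared within the rodo+ gate, in files whose headers name the same detectors. V431 was higher with E. Coli in both experiments, at 829 ± 11.7 (SD, n = 4) and 922 ± 35.8 (SD, n = 2) in replicates 1 and 3, against 645 ± 22.9, 722 ± 7.90 and 756 ± 1.05 (SD, n = 2 each) in Zymo replicates 1 to 3. The asinh difference was 0.210, with a two-sided exact permutation p of 0.1, the smallest possible for 2 against 3. B530 was 33620 ± 867 and 25964 ± 187 with E. Coli against 20016 ± 196 and 18020 ± 709 in Zymo replicates 2 and 3 (exact p = 0.333, the smallest possible). R670 had no common direction, at 9258 ± 336 and 24416 ± 346 with E. Coli against 18880 ± 99.7, 16368 ± 618 and 13592 ± 334 with Zymo (exact p = 0.9). YG was 3032 ± 99.9 and 1328 ± 263 against 1959 ± 105, 2386 ± 46.8 and 1064 ± 17.5 (exact p = 0.8). E. Coli replicate 3 and Zymo replicates 2 and 3 were recorded on the same day. The p-values over experiments nevertheless take them as independent units. Those units also rest on title numbers, which differ from the header in 8 of 12 libraries, so these p-values are uncertain. Within that day the asinh differences were 0.218 for V431, 0.313 for B530 and 0.49 for R670, each with an exact p of 0.0667 over 2 against 4 libraries (the smallest possible, adjusted p = 0.0889), and -0.191 for YG (exact p = 0.6). E. Coli replicate 2 came from another export with other filters and was not compared.

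Within most libraries, those of B16 rodo high, rodo+ and rodo- aside, cells with a higher YG reading were also brighter on R670 and V431. Spearman's rho across wells between YG and R670 was above 0 in 60 of 73 libraries, and between YG and V431 in 61 of 73. It averaged 0.522 for R670 and 0.563 for V431 in the 2 lung non-phago libraries, and 0.327 and 0.383 with forward scatter taken out. In the 4 lung phago libraries of replicate 3 rho with V431 lay between -0.357 and -0.294. In B16 tumours rho was above 0 for R670 in 3 of 6 rodo high and 4 of 8 rodo+ libraries, and for V431 in 3 of 6 and 5 of 8. For R670 this went by experiment, with means over replicates 1 to 3 of 0.151, -0.0409 and -0.0303 in rodo high and 0.240, -0.146 and -0.0417 in rodo+, where 4 of 4 libraries of replicate 1 were above 0 and 0 of 4 of the others. The coefficient was above 0 in 2 of 4 rodo- libraries for each, while in viable only, without added dye, it averaged 0.115 for R670 and 0.373 for V431 (4 of 4 above 0 for each). In vitro, rho with V431 was above 0 in every library: its mean over the experiments was 0.126 in phago and 0.307 in non-phago cells at 3 h, and 0.302 and 0.241 at 24 h. With B530 the sign depended on the group. It averaged -0.290 in B16 rodo high and -0.274 in rodo+ (0 of 14 libraries above 0, with Pearson's r of -0.415 in rodo+), but also -0.288 in viable only (0 of 4), against 0.0321 in rodo- (3 of 4), so the negative sign was also seen without added dye. In vitro it was -0.0655 in phago cells at 3 h (0 of 3) and 0.426 at 24 h (2 of 2). It was 0.138 in E. Coli and 0.307 in Zymo rodo+ (13 of 13 above 0). In lung phago cells rho with B530 was 0.382 over 2 experiments, and rho with forward scatter was 0.346 in the 4 libraries of replicate 2 that recorded it. With forward scatter taken out, rho with B530 was 0.436 and 0.425 in the 2 libraries of the first recording session, but 0.00306 and 0.0972 in the 2 of the second. Wells are not replicates, so no p was made from them, and over 3 experiments the exact sign-flip p was 0.25, the smallest possible, for B530 in both B16 gates and for R670 and V431 in the E. Coli and Zymo groups.

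**Figure D3:**
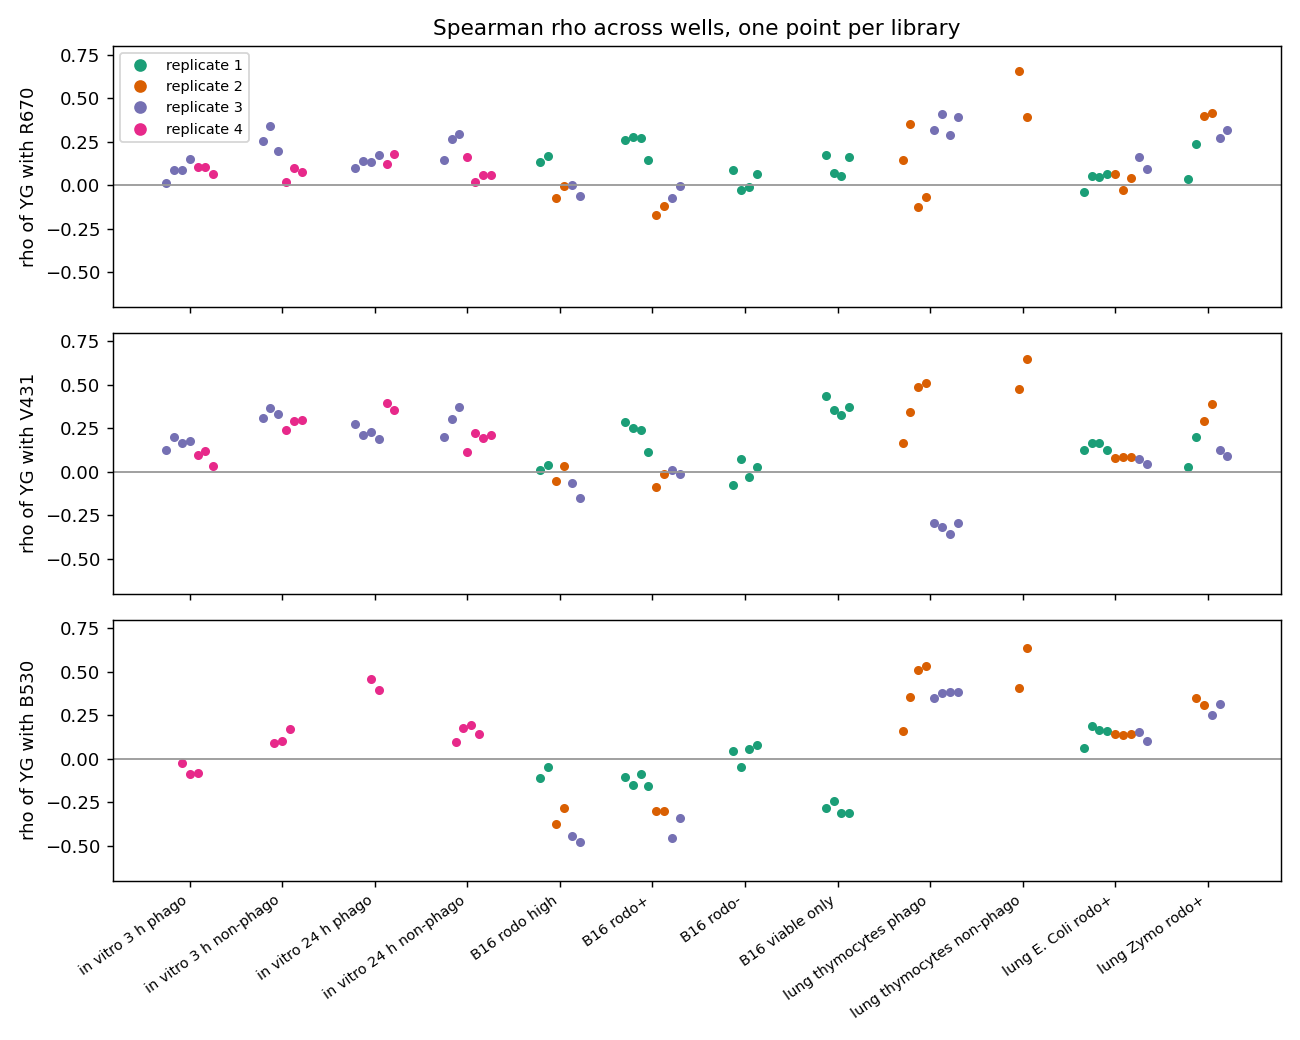
Spearman's rho across the wells of a library between the YG detector and R670, V431 or B530 (vertical axes, no unit), 1 point per library, coloured by replicate number.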

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

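The tests of a shift of all detectors and of the YG setting in the first pattern, of stray light, drift and tubes in the second, and of scatter settings, of R670 and of V431 in the third were chosen after the values they use had been seen. The other tests on matched wells and that on forward scatter within classes were fixed before their results were seen. The B530 value that divides the classes was, however, chosen after the values had been seen.

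A change of the gate difference with time stood out on YG and for rho with V431. The asinh difference of YG between phago and non-phago cells was smaller at 24 h than at 3 h, by -0.738 (24 h minus 3 h), with -1.01 in replicate 3 and -0.467 in replicate 4 (permutation of times over libraries, p = 2e-05, adjusted p = 0.00014 over 7 tests). The phago minus non-phago difference of rho of YG with V431 was higher at 24 h by 0.242. It went from -0.170 to -0.0673 in replicate 3 and from -0.193 to 0.189 in replicate 4 (permutation p = 0.00031, adjusted p = 0.001085). Both p-values are over plates of 2 experiments, and each time was recorded on its own day. The sort bounds YG in both gates, so it enters the YG change as well. In replicate 3 the lowest phago reading was 513 at 3 h and 465 at 24 h, and the highest non-phago reading 364 and 346. In replicate 4 these were 466 and 464, and 341 and 346. Their null is no change with time in either gate, so they do not test the gate difference alone.

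In the YG change, the higher reading of non-phago macrophages at 24 h was weighed first. A shift of all detectors between the days is argued against in replicate 3, where R670 differed by -0.174 ± 0.0435 (asinh, SD of the difference from 3 against 3 libraries), the other way. In replicate 4 R670 and V431 were higher with YG (0.186 and 0.143 beside 0.399), but B530 differed by -0.586 ± 0.0531, which argues against a shift of all detectors there, though a shift of some is not excluded. Brightness shared with V431 is argued against too, since at least 90.6% of the YG difference stayed in wells matched on V431 in both experiments. A YG setting that differed between days cannot be told apart from time, because phago cells can also have lost dye or dye brightness. The YG difference of phago cells was -0.0682 in the experiment with the smaller change. Uptake of small amounts of dye by cells below the gate is open too and was not tested.

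B16 rodo- cells stood above viable only cells on YG. Of this difference 83.9% stayed in wells matched on V431, R670 and V710 together (2309 of 3010 wells, in 64 bins). Cells within a bin can still differ on these detectors. V710 was not higher in rodo- (asinh difference -0.0408), so matching on it could remove little. That argues against brightness shared with these detectors as the whole cause. Wells were not matched on R780, which was also higher in rodo-, or on B530, so brightness shared with R780 or B530 was not tested. Light of the R670 or V710 stain reaching the YG detector is argued against as the whole cause too. Of the difference, 97.4% stayed in wells matched on these 2 detectors (2592 of 3010 wells). The range of viable only medians, 4.80% of the difference, comes from plates of 1 tube and says nothing about drift between tubes. Drift and background that differed between tubes remain open, since 0 tubes gave both groups, and a hypothesis that rodo- cells hold some dye rests on this experiment alone.

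Lung phago libraries of replicate 2 differed between the 2 recording sessions, as forward scatter was 1.84 times as high in the second. A changed forward scatter setting is argued against by the non-phago libraries, where this ratio was 0.980, though these were 1 library per session. A changed side scatter setting is argued against as the cause of the phago rise. The side scatter ratio was 2.34 in phago and 0.720 in non-phago libraries, the other way, and 0.846 and 1.09 within bright and dim phago wells. Different shares of 2 kinds of cell are a candidate explanation: a division at 454 units of B530, near which 4.74% and 1.97% of phago wells lay, put 22.2% of phago wells of the first session and 94.1% of the second in the bright class, and forward scatter within classes differed by ratios of 0.894 (bright) and 0.963 (dim). Shares give the direction for V431, whose mean median in phago libraries was 221 in the first session and 651 in the second, but shares alone do not account for R670 or V431, which were lower in the second session within the bright (ratios 0.675 and 0.655) and the dim class (0.63 and 0.457), as was B530 (0.787 and 0.517), on which the classes were set. A changed setting or staining for these detectors remains open, since dim non-phago wells were lower too (0.515 for R670 and 0.758 for V431) but came from 1 library per session, and whether the sort gate or the tissue differed was not tested.

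Libraries apart from the others of their experiment were found in 3 of the 44 sets of 4 or more libraries tested, beside the 1 in 20 that chance gives. All 3 were on B530, where 7 sets were tested, against 0 of 37 on the other detectors, and the cause was not tested. They were a B16 rodo+ library of replicate 1 at 2719 against 2912 to 2950, a 24 h non-phago library of replicate 4 at 445 against 465 to 468, and an E. Coli library of replicate 1 at 34910 against 33035 to 33283.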

How the results depend on the processing

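Using only the plates next to the change of gate, keeping wells with more than 1 event, leaving out E. Coli and Zymo experiments singly, and permuting lung libraries within recording sessions were chosen after the data had been seen, and the other alternatives were planned. Differences are of asinh medians unless stated otherwise. No test over experiments can pass 0.05 in this design, so an unchanged side of that threshold says nothing about stability, and direction is what was compared. For comparisons with 1 experiment, another scale was judged by its sign alone.

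With asinh cofactors of 5 and 1000, and on the log10 scale with values under 1 set to 1, all 76 results tried kept their direction. Keeping wells with more than 1 event and leaving out extreme wells kept the direction of 84 comparison results each, and of 56 coefficients each.

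Taking libraries as replicates put 24 results past the threshold with their differences unchanged, because this test counts plates and so has more arrangements. The 5 for YG between gates are set by the sort and say nothing, and the 16 for other detectors between gates also passed with YG left out of the adjustment, a choice made after the values had been seen. In vitro at 3 h these were 3.34 for YG, 0.117 for R670 and 0.0964 for V431, and at 24 h they were 2.61 for YG, 0.239 for R670 and 0.246 for V431. Between times they were -0.323 for YG and 0.189 for V431 in phago cells, and 0.416 for YG in non-phago cells. For rodo high minus rodo+ they were 1.104 for YG, 0.0890 for V431 and -0.253 for B530. For rodo+ minus rodo- they were 1.86 for YG, 0.340 for R670, 0.166 for V431, 0.346 for B530, 0.139 for R780 and 0.212 for V710. For rodo+ minus viable only they were 2.59 for YG, 0.637 for R670, 0.415 for V431, 0.305 for B530, 0.665 for R780 and 0.171 for V710.

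Permuting lung libraries within recording sessions left the 7 differences of phago minus non-phago as they were, and its smallest possible exact p, 0.111, cannot pass 0.05.

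The replicate block changed no direction and no call among 21 results. The difference within experiments at 3 h was 0.117 for R670, with an exact sign-flip p of 0.5, the smallest for 2 experiments, and for rodo high minus rodo+ on B530 it was -0.253, with an exact p of 0.25, the smallest for 3. E. Coli and Zymo numbers do not pair samples, so their block has no meaning of its own.

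The mean over wells in place of the median gave other sizes, and the cause was not tested. B530 was 0.382 for phago minus non-phago at 24 h and -0.676 for 24 h minus 3 h in non-phago cells. R670 of non-phago cells between times had the other sign, at -0.00488 against 0.00619. In B16, YG was 2.32 for rodo+ minus rodo-, 3.62 for rodo high minus rodo-, 0.676 for rodo- minus viable only, 2.99 for rodo+ minus viable only and 4.30 for rodo high minus viable only, and B530 was 0.261 for rodo+ minus rodo-.

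Only the plates next to the change of gate gave the same direction in 20 of 20 results. In vitro the value was 0.103 for R670 and 0.0894 for V431 at 3 h, and 0.199 for R670 at 24 h. For rodo+ minus rodo- it was 1.99 for YG, 0.0604 for R780 and 0.180 for V710. The cause was not tested.

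Leaving out an experiment gave the other sign for each difference in this paragraph except V431 and B530 of E. Coli minus Zymo, which were higher with E. Coli throughout. Between times R670 lay between -0.0363 and 0.291 in phago cells, and between -0.174 and 0.186 in non-phago cells, where V431 lay between -0.0635 and 0.143. For rodo high minus rodo+, R670 lay between -0.137 and 0.0384 and V710 between -0.0188 and 0.120. For E. Coli minus Zymo, experiments were left out singly and, as planned, by number, which takes out both particles' experiments of that number although numbers do not pair samples. YG lay between -0.260 and 0.573, R670 between -0.641 and 0.49, V431 between 0.158 and 0.262, and B530 between 0.313 and 0.571. YG was reversed without E. Coli replicate 1 (-0.260) or Zymo replicate 3 (-0.0785), and R670 without E. Coli replicate 1 (0.414) or Zymo replicate 1 (0.00795). Without number 1 they were -0.191 and 0.49, and the libraries of the day shared by both particles are the same subset, so their equal values are no second check.

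Leaving out a library reversed 3 differences near 0. R670 of non-phago cells between times was -0.00621 without a 3 h library of replicate 3, and between -0.00621 and 0.0129 over all libraries left out. R780 of rodo high minus rodo+ was -0.0265 without the first rodo high library recorded and 0.0681 without the other. V710 of rodo- minus viable only was 0.00335 without the last viable only library recorded and -0.103 without the first.

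Among coefficients of YG with another detector, 13 alternatives gave the other sign. When an experiment was left out, rho in rodo high lay between -0.0356 and 0.0601 for R670, -0.0560 and 0.00946 for V431, and -0.00920 and 0.0679 for V710. In rodo+ it lay between -0.0940 and 0.0990 for R670 and -0.0229 and 0.112 for V431. In lung phago cells it was -0.316 for V431 in replicate 3 alone and 0.378 in replicate 2 alone. Pearson's r in rodo- was -0.0540 for B530 and 0.0424 for V431. Pearson's r also moved 7 coefficients without a change of sign, most of all B530 in rodo+, from -0.274 to -0.415. When a library was left out, rho for R780 lay between -0.0434 and 0.0661 in rodo high. In rodo-, rho for V431 lay between -0.0263 and 0.0246, with 0.00852 without another library. In viable only, rho for R780 lay between -0.00684 and 0.0282, with -0.00615 without another library. The cause was not tested.

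Tests on genes and their alternatives were not run, because the readings hold no genes. Height in place of area was not run, because only areas are given. Taking out forward scatter was run only in the 9 libraries that recorded it, and it moved 6 of the 8 coefficients for which every library with the detector in that group had scatter. In lung phago cells R780 went from 0.201 to 0.0536, with libraries of both signs, and side scatter from 0.30 to 0.0809. In replicate 2 alone, which had scatter, R670 of phago cells turned from 0.0753 to -0.0493, with libraries between -0.189 and 0.157, V431 went from 0.378 to 0.238 and B530 from 0.391 to 0.240. In lung non-phago cells R670 went from 0.522 to 0.327, R780 from 0.516 to 0.349, V431 from 0.563 to 0.383 and B530 from 0.521 to 0.335. Each library has at least 356 wells, so the number of experiments limits the precision and not the number of cells.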

Other observations

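No value here was tested, and the values to give were chosen after the data had been seen. In lung non-phago libraries of replicate 2, YG went with every other reading, as mean rho over the 2 libraries was 0.447 with forward scatter, 0.529 with side scatter, 0.563 with V431, 0.521 with B530 and 0.522 with R670. With forward scatter taken out these were 0.355 for side scatter, 0.383 for V431, 0.335 for B530 and 0.327 for R670, the last with 0.631 in the first library and 0.0229 in the other. In phago libraries of replicate 3, rho of YG with V431 was -0.316 ± 0.0295 (SD, n = 4 libraries), against 0.378 ± 0.158 (SD, n = 4) in replicate 2. Up to 2.65% of the wells of a replicate 3 library read below 0 on V431.

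In B16 viable only libraries, recorded between 55.0 and 63.6 minutes after the first plate of the day, V710 medians were 10597, 12515, 13763 and 14580 in recording order, R670 medians were 7013, 7310, 7596 and 8822, and R780 medians were 52.2, 13.6, 1.36 and -19.2.

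E. Coli replicate 2, from the export with scatter, had a YG median of 13076 ± 657 (SD, n = 3 libraries) and rho of YG with forward scatter between 0.000994 and 0.0536. In E. Coli replicate 3 the mean of the 95th percentiles of YG was 79475 beside a median of 1328, while in the Zymo replicates recorded on that day it was 23665 and 10795 beside 2386 and 1064.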
